A study of Homo sapiens with 14 samples.

How the data were processed

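RNA was measured in 14 HEK 293 libraries: 3 controls, 2 with CFIm25 knockdown, 3 with CFIm25 overexpression, 3 with CFIm68 knockdown and 3 with CFIm68 overexpression. Groups and replicate numbers were taken from the labels. Per the labels' protocols, knockdown used siRNA with Lipofectamine RNAiMAX, and libraries were made from total RNA with a TruSeq Stranded mRNA kit. The deposited table holds raw read counts per gene, made by the authors from reads handled with cutadapt 1.16 and STAR 2.7.1a on hg38, per the submitters' processing notes. The counting tool, its annotation and its strand setting are not given in the sources used here. The values are whole numbers, and no normalization was found in them.

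The table has 18006 genes, of which 2524 are at 0 in every library, and 17959 identifiers matched a gene name. By the GENCODE 29 annotation 16911 are protein-coding, 1042 are lincRNA, 30 are of another type and 23 are not in that annotation. Of 967 single-exon protein-coding genes in the annotation 1 is in the table, at 0 counts, against 89.1% of 18971 multi-exon ones, and 0 mitochondrially encoded genes are in it. Genes without introns, such as most replication-dependent histones, are therefore outside the values reported here. HSPA8 and KLF6 are at 0 in every library, for a reason not given in the sources used here.

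Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 12080, and libraries were scaled by TMM, with factors of 0.973 to 1.05. A quasi-likelihood model with 1 coefficient per group was fitted to all 14 libraries, and p-values were adjusted by the Benjamini-Hochberg method over the tested genes of each comparison, with a threshold of 0.05. The 6 comparisons were each perturbed group against control, CFIm68 against CFIm25 knockdown, and CFIm68 against CFIm25 overexpression. The square root of the common dispersion was 0.0501. Standard errors of log2 changes come from the quasi-likelihood statistic. Coordinates are those of GENCODE 29 on hg38.

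Before the data were examined, 29 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. The rule names NUDT21, CPSF6 and CPSF7. It adds the 8 higher and 8 lower genes with the largest change in each comparison with control, or 5 and 5 in the direct comparisons, among genes past the threshold with a mean of at least 5 CPM and no overlap between libraries. It then adds the 3 members with the smallest adjusted p of each called list, 2 of each list that was not called, and any member past the threshold of the 3' end processing, microRNA pathway and published CFIm target lists. The report names a part of them. Values of some genes under this rule are not reported here. Of the lists, 27 had at least 5 tested members and were tested with camera from limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether the members move one way and does not compare them with other genes, were run beside it.

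Fold changes against the same 3 controls are correlated by construction. For each pair of comparisons 50 simulated data sets without group effects, drawn from the control means and the fitted dispersions, gave the correlation and covariance that shared controls alone produce. For CFIm25 knockdown and overexpression, fold changes were also taken against separate control libraries, 1 for one comparison and the others for the other, in all 6 ways. The gene test was checked on simulated counts for 11830 genes with known changes. Of genes changed 1.5-fold, 76% were recovered for CFIm25 knockdown, 88% for CFIm25 overexpression, 84% for CFIm68 knockdown and 84% for CFIm68 overexpression, and of genes changed 2-fold 94%, 96%, 100% and 100%. Between 6 and 11 unchanged genes were called. A seeded list was called and 0 of 26 other lists were called by camera. The simulated genes were drawn independently of each other. This check therefore cannot show how often camera calls lists of correlated genes, as real genes may be.

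Alternatives were median-ratio size factors, no filter, a filter of at least 1 CPM in at least 3 libraries, the replicate number as a block, DESeq2 1.42.0 and limma-voom in place of edgeR, a fit to the compared groups alone, and leaving out each library. Chosen after the data were seen were the removal of medians of windows of 50 neighbouring genes and the use of the overexpression groups as further references. Exons of 122 named genes were compared with those of other GENCODE 29 genes, and 10 share bases with another gene on the same strand and 51 with another gene on either strand. Polyadenylation site use and 3' UTR length of transcripts were not analysed here, since counts per gene do not hold them. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.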

Results

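Gene-level read counts were compared across 14 RNA-seq libraries of HEK 293 cells, an established human embryonic kidney cell line. The libraries fall into 5 groups: control (n = 3), knockdown of CFIm25 (n = 2), overexpression of CFIm25 (n = 3), knockdown of CFIm68 (n = 3) and overexpression of CFIm68 (n = 3). CFIm25, encoded by NUDT21, and CFIm68, encoded by CPSF6, are subunits of the cleavage factor I complex, which binds pre-mRNA upstream of cleavage sites and favours distal polyadenylation sites. Knockdown used small interfering RNA. Controls carry a wild-type label, and whether they received a control siRNA or an empty vector is not given in the sources used here. Total counts per library were 17734490 to 18385536 in control, 22464083 and 33895308 in CFIm25 knockdown, 16437307 to 23125253 in CFIm25 overexpression, 24119597 to 28963694 in CFIm68 knockdown and 15822467 to 18297610 in CFIm68 overexpression. Within groups, log2 CPM (counts scaled to a common library size) correlated across genes at r = 0.993 to 0.997, and 12080 genes were tested. Nothing states that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. CPM values below are group means ± SD, and log2 changes are given ± SE.

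The first question was whether each subunit's own transcript moved as its group label says. NUDT21 (chromosome 16, 56429133 to 56452199, hg38) stood at 514 ± 19.6 CPM in control and at 53.8 ± 1.2 CPM in CFIm25 knockdown, 9.57-fold lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 3.5e-23). In CFIm25 overexpression it reached 729 ± 55.6 CPM, 1.42-fold above control (edgeR adjusted p = 2.0e-08). CPSF6 (chromosome 12, 69239537 to 69274358) fell from 268 ± 5.78 CPM in control to 41.6 ± 0.996 CPM in CFIm68 knockdown, 6.44-fold (edgeR adjusted p = 3.2e-25), and rose to 730 ± 17.4 CPM in CFIm68 overexpression, 2.72-fold (edgeR adjusted p = 1.3e-19). The other subunit's transcript moved as well. CPSF6 rose 1.99-fold in CFIm25 knockdown, to 533 ± 10.2 CPM, whereas NUDT21 fell 2.21-fold in CFIm68 knockdown, to 232 ± 9.27 CPM. NUDT21 also rose in CFIm68 overexpression (log2 change 0.22 ± 0.06, edgeR adjusted p = 4.9e-03), a call lost with the medians of neighbouring genes removed (0.09, adjusted p = 0.32). CPSF6 in CFIm25 overexpression had a log2 change of -0.09 ± 0.05 that did not pass (edgeR adjusted p = 0.12). CPSF7 (chromosome 11, 61402641 to 61430031), which encodes the alternative large subunit CFIm59, fell in CFIm25 knockdown (-0.42 ± 0.06) and in CFIm68 knockdown (-0.24 ± 0.05), and did not pass in either overexpression group (-0.01 ± 0.05 with CFIm25 and 0.10 ± 0.05 with CFIm68). With the medians of neighbouring genes removed it passed as a rise in CFIm25 overexpression (0.13, adjusted p = 0.032). Counts do not separate transcripts of the resident gene from those of an introduced copy.

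**Figure D1:**
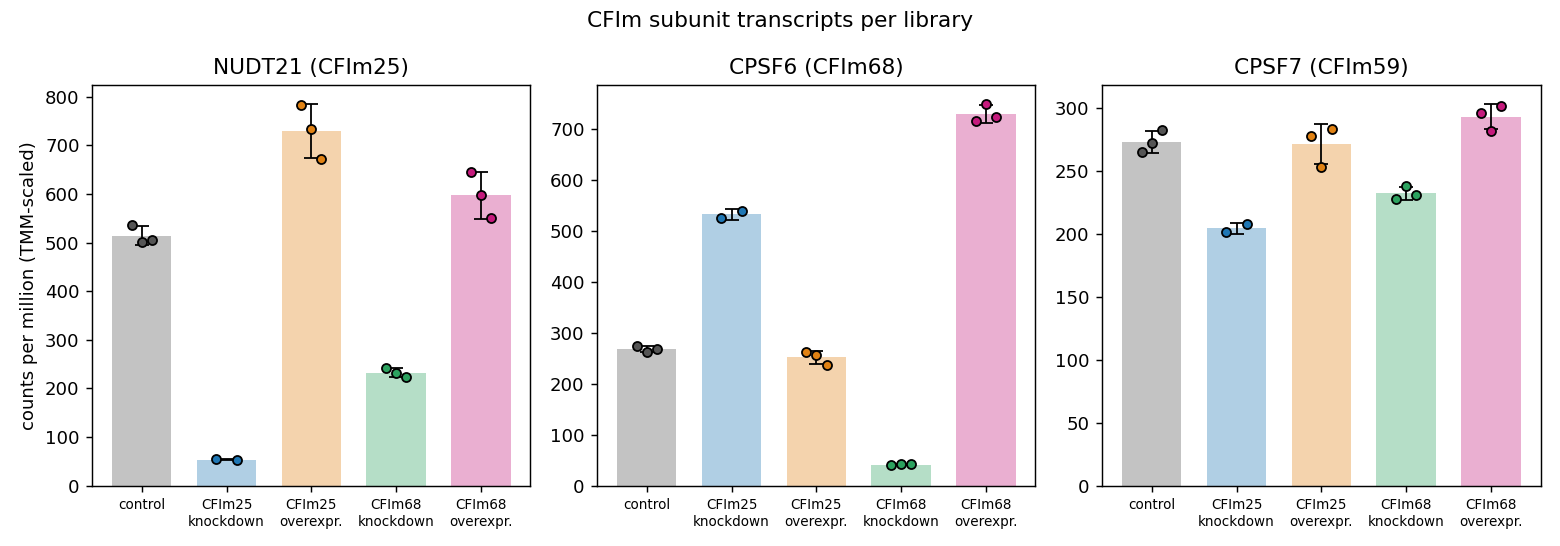
TMM-scaled CPM of NUDT21, CPSF6 and CPSF7 in each library (points), with the group mean (bar) and SD (error bar; n = 3 libraries, n = 2 for CFIm25 knockdown). NUDT21 is lowest in CFIm25 knockdown, at 53.8 CPM, and CPSF6 is lowest in CFIm68 knockdown, at 41.6 CPM, and stands at 533 CPM in CFIm25 knockdown.

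Genes named for the size of their change had a mean of at least 5 CPM over the libraries compared and no overlap between the groups. CFIm25 knockdown raised TENM1, a teneurin adhesion receptor, from 8.93 ± 1.98 to 36.4 ± 0.897 CPM (log2 change 2.03 ± 0.10, edgeR adjusted p = 5.5e-15). VMA21, an assembly factor of the vacuolar ATPase and a published target of CFIm-dependent polyadenylation, rose 3.51-fold, and BST2, an interferon-induced antiviral membrane protein, rose 3.5-fold. TSC22D3, a glucocorticoid-induced leucine zipper protein that was already at 429 ± 24.2 CPM in control, rose 3.02-fold, as did SDHAF4, an assembly factor of succinate dehydrogenase. MYH15, ZNF780A and the glycosyltransferase gene MGAT4A rose by log2 changes of 1.87 ± 0.14, 1.55 ± 0.08 and 1.54 ± 0.13. Apart from NUDT21, the steepest falls among genes with a mean of at least 5 CPM were in MAMDC4 (-2.42 ± 0.20), the protocadherin gene PCDH20 (-2.19 ± 0.12), GDPD3 (-2.14 ± 0.20) and TMEM86B (-2.14 ± 0.15). At that level they were followed by the protease gene PRSS53 (-2.12 ± 0.16), the reticulocalbin gene RCN3 (-1.94 ± 0.19) and BRICD5 (-1.85 ± 0.14). In all, 5746 genes changed (47.6% of those tested; edgeR adjusted p under 0.05), 2949 higher and 2797 lower, and 210 rose and 270 fell at least 2-fold. MAMDC4, PCDH20 and PRSS53 share exonic bases with another gene on the same strand, so their counts may be split between genes.

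Lists are called below by camera at its preset correlation unless another test is named. In the comparisons of 3 with 3 libraries, at least 1 other split of the same libraries called as many lists or more, as given further below. Among gene lists, cytosolic ribosomal proteins, the protein part of the ribosome, moved most evenly in CFIm25 knockdown. Of 73 tested members 52 rose, 0 fell and 21 did not pass (52 and 0 adjusted over the list alone), with a median log2 change of 0.29, and RPL30 (0.77 ± 0.05), RPL36 (0.71 ± 0.06) and RPL37 (0.58 ± 0.06) led. The camera test gave an adjusted p of 2.3e-14 at its preset correlation, and adjusted p = 0.44 with an estimated correlation. Targets of the tumour suppressor p53 went the other way. Of 24, 1 rose, 16 fell and 7 did not pass (2 and 16 adjusted over the list alone). Among them were PHLDA3 (-1.32 ± 0.08), the apoptosis effector BAX (-0.70 ± 0.08) and TP53INP1 (-0.65 ± 0.08). The list had a camera adjusted p of 1.4e-04 and adjusted p = 0.16 with an estimated correlation. The list of the unfolded protein and ATF4 stress response had 18 of 33 members higher, 7 lower and 8 not past the test (18 and 7 over the list alone), and was called at a camera adjusted p of 0.0049, with adjusted p = 0.44 with an estimated correlation. Its leading members were the amino acid genes ASNS (1.06 ± 0.09) and SLC7A11 (1.13 ± 0.12) and the folate enzyme gene MTHFD2 (0.70 ± 0.07). SLC7A11 varied widely within the group, at 179 ± 61 CPM. Oxidative phosphorylation had 16 of 38 members higher, 4 lower and 18 not past (16 and 4 over the list alone), led by COX6C (0.68 ± 0.07) and COX7C (0.51 ± 0.06). Its camera adjusted p was 0.035 and adjusted p = 0.74 with an estimated correlation. Without CFIm25 knockdown replicate 1 the stress and the oxidative phosphorylation lists missed the threshold (camera adjusted p = 0.055 for both), and the latter also missed it without control replicate 1 (0.051) or control replicate 2 (0.16). Leaving out control replicate 2 left 3 called lists in place of 5.

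Among genes with a mean of at least 5 CPM, CFIm68 knockdown gave its largest rise in PHF7, a PHD finger protein, from a control level of 1.04 ± 0.28 CPM (log2 change 3.26 ± 0.18, edgeR adjusted p = 8.4e-15). The cyclin gene CCND2 rose from 31.0 ± 1.52 to 150.3 ± 6.5 CPM, 4.84-fold. VMA21 rose 4.96-fold, TENM1 4.3-fold, the methionine adenosyltransferase gene MAT1A 4.29-fold and BST2 4.16-fold. MGAT4A rose 3.47-fold and GRK3, which encodes a kinase that acts on G protein-coupled receptors, 3.45-fold. PDIA3, an abundant disulfide isomerase of the endoplasmic reticulum, fell from 618 ± 30.1 to 122 ± 3.28 CPM (-2.35 ± 0.05, edgeR adjusted p = 9.2e-24). HNRNPLL, a splicing regulator, fell 5.6-fold, PRSS53 5.34-fold, PCDH20 5.23-fold, the small GTPase gene RAB9B 4.63-fold, TMEM86B 4.4-fold and PABIR2 4.29-fold. A total of 6811 genes changed (56.4% of those tested), 3414 higher and 3397 lower, with 320 up and 361 down at least 2-fold. CCND2 also shares exonic bases with another gene on the same strand, and PDIA3 overlaps exons of genes on the opposite strand, which matters only if strand was ignored in counting.

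Ribosomal protein genes rose here too. Of 73, 61 were higher, 0 were lower and 12 did not pass (61 and 0 adjusted over the list alone), with a median log2 change of 0.28 and RPL36 (0.76 ± 0.05), RPL30 (0.68 ± 0.05) and RPL26 (0.56 ± 0.05) in the lead. Camera gave an adjusted p of 2.8e-12, and adjusted p = 0.51 with an estimated correlation. RPL36 and RPL26 share exonic bases with another gene on the same strand. The other lists called in CFIm25 knockdown, apart from published CFIm targets, were not called here: p53 targets had 3 of 24 higher and 10 lower (camera adjusted p = 0.19), the stress list 11 of 33 higher and 8 lower (0.66) and oxidative phosphorylation 14 of 38 higher and 11 lower (0.44). The spliceosome and SR protein list had 18 of 40 members lower, 5 higher and 17 not past (19 and 5 over the list alone), including SRSF7 (-0.66 ± 0.05), TRA2A (-0.91 ± 0.07) and EFTUD2 (-0.52 ± 0.05). Its camera adjusted p was 0.037, with adjusted p = 0.51 with an estimated correlation, and it missed the threshold without control replicate 3 (0.081), without CFIm68 knockdown replicate 3 (0.0501) and with the medians of neighbouring genes removed (0.058). The 3' end processing list, which holds the CFIm subunits themselves, was not called by camera (adjusted p = 0.051), while fry called it as lower (fry adjusted p = 1.1e-05). Of 21 members 6 rose, 10 fell and 5 did not pass. Beside CPSF6, NUDT21 and CPSF7 the endonuclease partner gene CPSF2 rose (0.58 ± 0.05) while the scaffold gene CPSF1 (-0.46 ± 0.05) and the phosphatase gene SSU72 (-0.36 ± 0.06) fell. In CFIm25 knockdown the same list had 8 higher, 6 lower and 7 not past, with a median of 0.01 and a mean of -0.10. Camera did not call it (adjusted p = 0.63), while fry called it as lower (fry adjusted p = 0.035). There CPSF2 rose (0.57 ± 0.06) and CPSF1 (-0.49 ± 0.06) and SSU72 (-0.54 ± 0.06) fell. With the medians of neighbouring genes removed, SSU72 did not pass in CFIm25 knockdown (-0.15) and stood at 0.03, of the other sign, in CFIm68 knockdown, and CPSF1 did not pass in CFIm68 knockdown (-0.12).

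A further question, named in the series title, was what the complex does to signalling and microRNA biogenesis genes. A list of 14 genes published as targets of CFIm-dependent 3' UTR choice, 12 of them tested, had 8 higher, 3 lower and 1 not past in CFIm25 knockdown and 9 higher, 3 lower and 0 not past in CFIm68 knockdown, with the same counts adjusted over the list alone. VMA21 led both. DICER1, the microRNA-processing endonuclease, rose by 1.19 ± 0.18 and 1.36 ± 0.16. The kinase gene GSK3B rose by 0.55 ± 0.07 and 0.83 ± 0.07. FHL1 (-0.36 ± 0.06 and -0.69 ± 0.05) and PAK1 (-0.25 ± 0.06 and -0.67 ± 0.06) fell in both. The list's camera adjusted p was 0.035 in CFIm25 knockdown and 0.016 in CFIm68 knockdown, with adjusted p = 0.44 and 0.51 with an estimated correlation. In CFIm25 knockdown that call was lost without control replicate 2 (0.060) or control replicate 3 (0.075), with no filter on low counts (0.058), with the replicate number as a block (0.059) and with the medians of neighbouring genes removed (0.084).

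Camera did not call the microRNA pathway list, and its members moved both ways. Fry called it as higher in CFIm68 knockdown (fry adjusted p = 0.022) and did not call it in CFIm25 knockdown (0.44). In CFIm25 knockdown 8 of 28 rose, 7 fell and 13 did not pass (camera adjusted p = 0.77; median -0.04, mean 0.07), and in CFIm68 knockdown 11 rose, 9 fell and 8 did not pass (camera adjusted p = 0.44). Among single members, TNRC6B, which encodes a scaffold protein of the silencing complex, rose by 1.08 ± 0.09 and 1.64 ± 0.08 (edgeR adjusted p = 1.2e-10 and 6.9e-16). The argonaute gene AGO4 rose by 0.53 ± 0.07 and 0.92 ± 0.06, and AGO2 by 0.50 ± 0.08 and 0.78 ± 0.07. DROSHA, the nuclear microRNA-processing endonuclease, changed by -0.31 ± 0.06 and -0.46 ± 0.05, its partner DGCR8 by -0.37 ± 0.07 and -0.28 ± 0.06, and the helicase genes DDX17 by -0.36 ± 0.06 and -0.37 ± 0.06 and DDX5 by -0.26 ± 0.06 and -0.30 ± 0.05. With the medians of neighbouring genes removed DGCR8 did not pass in CFIm25 knockdown (-0.16). XPO5, which exports precursor microRNAs, fell in CFIm68 knockdown (-0.34 ± 0.04). Among 6 tested microRNA host transcripts, MIR34AHG, the host of a p53-regulated microRNA, fell in both (-1.42 ± 0.11 and -1.31 ± 0.10). The list had 0 higher, 3 lower and 3 not past in CFIm25 knockdown and 1 higher, 2 lower and 3 not past in CFIm68 knockdown. Camera did not call it (adjusted p = 0.19 and 0.44), while fry called it as lower in both (fry adjusted p = 0.0013 and 0.0029).

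**Figure D2:**
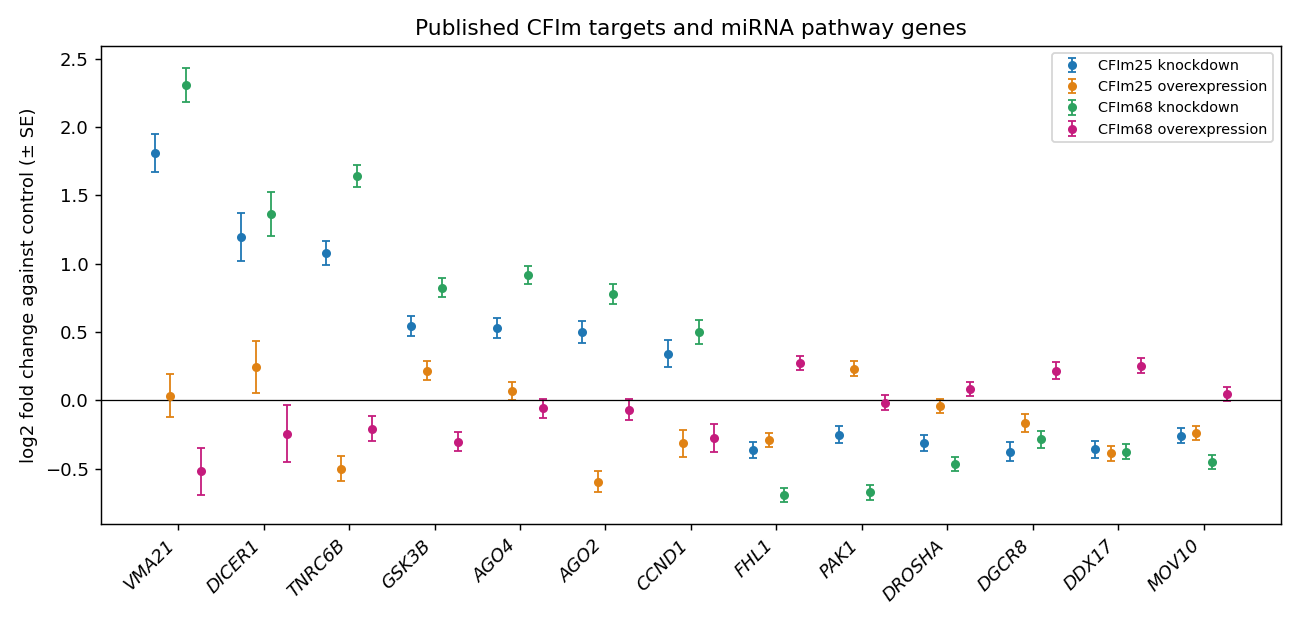
Log2 fold change against control (y axis, point with SE bar) of 13 genes from the lists of published CFIm targets and the microRNA pathway, in each of the 4 perturbed groups (colours). VMA21, DICER1 and TNRC6B rise most in the knockdowns, up to 2.31 for VMA21 in CFIm68 knockdown, and DROSHA and DGCR8 fall in both.

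Camera called no signalling list in either knockdown, while fry, which does not compare a list with other genes, called WNT and NOTCH in both and TGF-beta and BMP in CFIm68 knockdown. In CFIm25 and CFIm68 knockdown, respectively, the RAS-MAPK list had 10 and 10 of 38 members higher and 10 and 9 lower, and PI3K-AKT-mTOR 14 and 13 of 34 higher and 9 and 10 lower. In the same order, WNT had 5 and 7 of 27 higher and 9 and 7 lower, TGF-beta and BMP 8 and 7 of 29 higher and 8 and 7 lower, and Hippo-YAP 5 and 4 of 23 higher and 6 and 5 lower. NOTCH had 2 and 5 of 28 higher and 10 and 11 lower (camera adjusted p = 0.087 and 0.14). Genes that rose in both knockdowns included the kinase gene BRAF (0.81 ± 0.08 and 1.11 ± 0.07) and the activin receptor gene ACVR2B (1.12 ± 0.10 and 1.37 ± 0.09). Falling in both were the frizzled receptor gene FZD5 (-0.81 ± 0.06 and -1.42 ± 0.06) and NOTCH1 (-0.95 ± 0.09 and -0.97 ± 0.08). Not called by camera either were the interferon response (11 and 10 of 26 higher, 5 and 5 lower), DNA replication (16 and 17 of 39 higher, 9 and 14 lower), lysosome and V-ATPase (10 and 11 of 33 higher, 12 and 14 lower). The same holds for cholesterol synthesis, hypoxia and glycolysis, mitosis, neuronal, extracellular matrix and ZNF-named lists, and for 5 tested replication-dependent histone genes (0 and 0 higher, 1 and 0 lower). Of these, fry called the interferon response as higher in both knockdowns (fry adjusted p = 4.1e-04 and 1.3e-04). In CFIm25 knockdown it also called DNA replication as higher (fry adjusted p = 0.0012) and the histone genes as lower (0.0085). Median, mean and test did not share a sign for RAS-MAPK, PI3K-AKT-mTOR, TGF-beta, lysosome, cholesterol, mitosis, DNA replication and hypoxia lists in at least 1 knockdown, nor for the stress list in CFIm68 knockdown. Among markers of other cell types, 4 of 6 keratinocyte and HeLa-type epithelial genes rose and 0 fell in each knockdown. KRT17 was at 4.1 ± 0.303 CPM in control and 11.9 ± 2.23 CPM in CFIm68 knockdown. Of 5 mesenchymal genes 2 rose and 0 fell in each. Camera called neither list, and fry called both as higher in both knockdowns. The list of blood cell markers had 3 tested members and that of mitochondrially encoded genes 0, so neither was tested.

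Set against each other, the 2 knockdowns went together across genes, with r = 0.83 between their log2 changes over 12080 genes (genes are not independent replicates). Unchanged groups simulated against the same controls gave r = 0.52 ± 0.021, and the covariance was 0.202 against a simulated 0.0148. Of 4475 genes past the threshold in both, 2229 were higher in both and 2136 lower in both, where lists drawn independently would share 833 and 787, and 97.5% went the same way. Separate control libraries for each comparison, as used further below for other pairs, were not tried for this pair. Part of the excess may therefore come from the shared controls. Both knockdowns used siRNA, and whether control cells were transfected is not given. An effect of transfection shared by the 2 knockdowns therefore cannot be told apart from one of CFIm loss.

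In the direct comparison of CFIm68 with CFIm25 knockdown, PDIA3 was 4.3-fold lower with CFIm68 knockdown (522 ± 16.4 against 122 ± 3.28 CPM). TSFM, a mitochondrial translation elongation factor, was 3.81-fold lower, BABAM1, a subunit of the BRCA1-A complex, 3.02-fold lower and the glucosamine-phosphate isomerase gene GNPDA1 2.97-fold lower (edgeR adjusted p = 3.0e-17). The secreted hormone gene STC1 was 2.65-fold higher, the bicarbonate transporter gene SLC4A8 2.41-fold, SNX16 2.09-fold and PHLDA3 2.07-fold higher. NUDT21 was 4.33-fold higher and CPSF6 12.8-fold lower. Altogether 2929 genes differed (1340 higher and 1589 lower in CFIm68 knockdown; edgeR adjusted p under 0.05), of which 35 and 45 differed at least 2-fold; without CFIm25 knockdown replicate 1 the count was 1465. TSFM and BABAM1 share exonic bases with another gene on the same strand.

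Between the knockdowns 5 lists were called, each with adjusted p = 0.78 with an estimated correlation. The unfolded protein and ATF4 stress list was lower with CFIm68 knockdown (8 of 33 higher, 18 lower and 7 not past; 9 and 18 over the list alone; camera adjusted p = 0.013), with ATF4 itself at -1.02 ± 0.07 and SLC7A11 at -1.48 ± 0.12. Spliceosome genes were also lower (1 of 40 higher, 10 lower and 29 not past; 1 and 12 over the list alone; camera adjusted p = 0.013), led by EFTUD2 (-0.74 ± 0.05). Extracellular matrix genes were higher (10 of 33 higher, 2 lower and 21 not past; 13 and 2 over the list alone; camera adjusted p = 0.015), with VIM at 0.39 ± 0.05 and MMP2 at 0.70 ± 0.11. The p53 targets were higher too (10 of 24 higher, 2 lower and 12 not past, the same over the list alone; camera adjusted p = 0.015), with CDKN1A, the cell cycle inhibitor p21, at 0.67 ± 0.11. The 3' end processing list (4 of 21 higher, 3 lower and 14 not past; 4 and 4 over the list alone) was called at 0.049. Without CFIm25 knockdown replicate 1 the stress list (0.16) and the matrix list (0.051) missed the threshold, the p53 list did so without CFIm25 knockdown replicate 2 (0.088), and the 3' end list without each CFIm68 knockdown replicate (0.20, 0.12 and 0.086). The 3' end call was also lost with no filter on low counts (0.51), with the replicate number as a block (0.17) and with the medians of neighbouring genes removed (0.079). Fitting the libraries of these groups alone left 2 called lists, with stress, p53 and 3' end lists at camera adjusted p of 0.082, 0.057 and 0.10.

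In the CFIm25 overexpression libraries several genes were nearly absent, and the causes weighed further below do not settle why. CD99, a cell surface glycoprotein gene, went from 57.2 ± 4.72 to 0.129 ± 0.0744 CPM (log2 change -8.82 ± 0.17, edgeR adjusted p = 1.3e-25). PNMA8A went from 11.4 ± 1.73 to 0.0713 ± 0.037 CPM and PCDH20 from 21.8 ± 1.79 to 0.309 ± 0.14 CPM. GSTP1, an abundant glutathione transferase gene, fell 16.8-fold to 7.56 ± 0.406 CPM, the transcription factor gene STAT6 fell 13.2-fold, the DNA sensor gene IFI16 fell from 12.8 ± 1.03 to 1.05 ± 0.0918 CPM, CXXC4 9.47-fold and TMEM200B 8.11-fold. On the other side, TPTE, a phosphatase-like gene with near-identical copies elsewhere in the genome, had 589 counts in all against 3 in control (ratio 182, 95% exact counting interval 61.9 to 885). SLC7A11, which imports cystine, rose 6.4-fold, the glycine transporter gene SLC6A9 5.08-fold, CHAC1, which degrades glutathione, 7.11-fold, the protocadherin gene PCDH19 4.64-fold, TSC22D3 4.45-fold, ZNF83 4.35-fold and FAM184B 4.28-fold. In total 6854 genes changed (56.7% of those tested), 3343 higher and 3511 lower, with 396 up and 259 down at least 2-fold.

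Cholesterol synthesis genes fell together in CFIm25 overexpression: of 27 members 1 rose, 23 fell and 3 did not pass (1 and 24 adjusted over the list alone), including HMGCS1 (-1.25 ± 0.08), MSMO1 (-1.20 ± 0.09) and SQLE (-0.94 ± 0.07). Camera gave an adjusted p of 8.5e-10, and adjusted p = 0.13 with an estimated correlation. The unfolded protein and ATF4 stress list rose, with 22 of 33 higher, 8 lower and 3 not past (23 and 8 over the list alone). ASNS stood at 2.06 ± 0.09 and the amino acid transporter gene SLC7A5 at 1.44 ± 0.07 (camera adjusted p = 8.5e-10; adjusted p = 0.13 with an estimated correlation). Of 378 ZNF-named zinc finger genes 190 rose, 41 fell and 147 did not pass (192 and 42 over the list alone). Among them were ZNF43 at 1.37 ± 0.08 and ZNF711 at 1.05 ± 0.06 (camera adjusted p = 1.7e-06; adjusted p = 0.20 with an estimated correlation). Neuronal genes had 8 of 20 higher, 1 lower and 11 not past, the same over the list alone. They were led by SYP, synaptophysin, at 1.58 ± 0.09, and CHGB at 1.42 ± 0.15 (camera adjusted p = 0.014, and 0.13 with an estimated correlation). Keratinocyte and HeLa-type epithelial genes had 3 of 6 higher and 0 lower, and mesenchymal genes 0 of 5 higher and 2 lower. Camera called neither (adjusted p = 0.30 and 0.61), while fry called the first as higher and the second as lower (fry adjusted p = 4.5e-04 and 5.9e-04).

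Further lists fell in CFIm25 overexpression, each with adjusted p = 0.42 with an estimated correlation unless another value is given. Mitosis genes had 26 of 39 lower, 2 higher and 11 not past (camera adjusted p = 4.2e-06), with the spindle checkpoint kinase gene BUB1 at -0.94 ± 0.05 and PLK1 at -0.75 ± 0.05. Oxidative phosphorylation had 25 of 38 lower, 3 higher and 10 not past (camera adjusted p = 6.3e-05), with ATP5MC3 at -0.75 ± 0.05. Extracellular matrix genes had 16 of 33 lower, 4 higher and 13 not past (camera adjusted p = 6.2e-04), led by SPARC, a matrix glycoprotein gene, at -1.59 ± 0.05, and over the list alone the counts for these 3 lists were unchanged. Lysosome and V-ATPase genes had 21 of 33 lower, 3 higher and 9 not past (22 and 3 over the list alone; camera adjusted p = 0.0024), with ATP6V0D1 at -0.68 ± 0.06. The spliceosome list had 24 of 40 lower, 7 higher and 9 not past, the same over the list alone (camera adjusted p = 0.023; adjusted p = 0.43 with an estimated correlation), with SF3B3 at -0.45 ± 0.04. It missed the threshold without control replicate 3 (0.051) or CFIm25 overexpression replicate 2 (0.052). The microRNA pathway had 14 of 28 lower, 5 higher and 9 not past and was not called by camera (adjusted p = 0.060), while fry called it as lower (fry adjusted p = 2.3e-04). AGO1 (-0.64 ± 0.09), AGO2 (-0.59 ± 0.08), SRRT (-0.60 ± 0.06) and TNRC6B (-0.50 ± 0.09) fell, and with the medians of neighbouring genes removed AGO2 stood at 0.12 and did not pass. Published CFIm targets had 2 of 12 higher, 6 lower and 4 not past. Camera did not call them (adjusted p = 0.63), while fry called them as lower (fry adjusted p = 0.021).

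CFIm68 overexpression changed fewer genes, 3605 (29.8% of those tested; edgeR adjusted p under 0.05), 1746 higher and 1859 lower, with 90 up and 243 down at least 2-fold. With the medians of neighbouring genes removed the count was 2269. Among genes with a mean of at least 5 CPM over both groups, ZNF83 fell furthest, from 9.94 ± 0.573 to 0.141 ± 0.0228 CPM (-6.07 ± 0.26, edgeR adjusted p = 3.0e-17), followed by the growth factor gene PDGFD, from 24.4 ± 0.78 to 0.371 ± 0.175 CPM. The steroid sulfatase gene STS fell 16.2-fold, ZNF468 15.9-fold, ZNF816 by a log2 change of -3.81 ± 0.15, the phospholipase gene PLA2G4A 10.4-fold, ZNF681 9.73-fold and PUDP, the X-linked neighbour of STS, 9.23-fold. Apart from CPSF6, the largest rises at that level were in MXRA8 (1.76 ± 0.13), PNMA8A (1.72 ± 0.10), SHISA2 (1.53 ± 0.07), GRAMD2A (1.52 ± 0.18), the thrombospondin gene THBS4 (1.47 ± 0.06), BST2 (1.38 ± 0.15) and ADAMTS18 (1.35 ± 0.10). ZNF468 and ZNF816 share exonic bases with other genes on the same strand, and zinc finger genes are similar in sequence, so single values are uncertain.

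In CFIm68 overexpression 4 lists were called. Of 5 tested mesenchymal markers 0 rose, 3 fell and 2 did not pass, the same over the list alone, with the collagen gene COL1A1 at -0.88 ± 0.07 (camera adjusted p = 0.0011; adjusted p = 0.064 with an estimated correlation). Hypoxia and glycolysis genes had 12 of 27 lower, 2 higher and 13 not past (14 and 2 over the list alone), including the hexokinase gene HK2 (-0.63 ± 0.07) and the mitophagy receptor genes BNIP3 (-0.68 ± 0.10) and BNIP3L (-0.75 ± 0.09). The list had a camera adjusted p of 0.0014 and adjusted p = 0.68 with an estimated correlation. The unfolded protein and ATF4 stress list rose again, with 15 of 33 higher, 3 lower and 15 not past (16 and 5 over the list alone). SLC7A5 stood at 0.75 ± 0.07 and PSAT1 at 0.58 ± 0.07 (camera adjusted p = 0.0015; adjusted p = 0.51 with an estimated correlation). NOTCH signalling had 8 of 28 higher, 1 lower and 19 not past (10 and 1 over the list alone). It was led by its ligand gene JAG1 (0.47 ± 0.06) and NOTCH1 (0.58 ± 0.08; camera adjusted p = 0.014; adjusted p = 0.44 with an estimated correlation). The microRNA pathway (3 of 28 higher, 5 lower, 20 not past) and the published CFIm targets (1 of 12 higher, 5 lower, 6 not past) were not called by camera (adjusted p = 0.88 and 0.28). Fry called the published targets as lower (fry adjusted p = 0.014) and did not call the microRNA pathway (0.78).

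**Figure D3:**
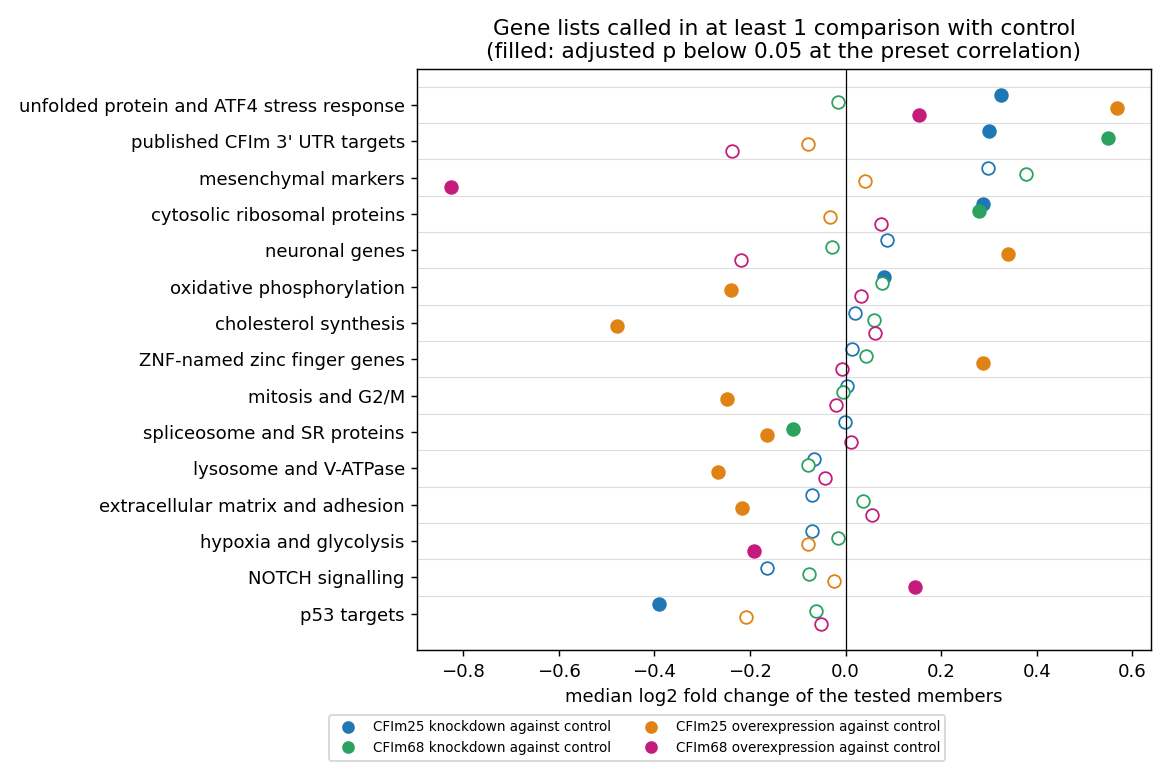
Median log2 fold change of the tested members (x axis) of each gene list called in at least 1 comparison with control, for the 4 comparisons (colours); filled points passed camera's adjusted p of 0.05 at its preset correlation. Cytosolic ribosomal proteins are called in both knockdowns, with medians of 0.29 and 0.28, and cholesterol synthesis is called in CFIm25 overexpression alone, with a median of -0.48.

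The overexpression groups did not go together. Their log2 changes had r = -0.08, against 0.50 in simulated unchanged groups, with a covariance of -0.0231 against a simulated 0.0148, and of 2322 genes past the threshold in both, 438 were higher in both, 447 lower in both and 1437 opposite. Compared directly, PNMA8A was at 37.7 ± 2.36 CPM with CFIm68 and at 0.0713 ± 0.037 CPM with CFIm25 overexpression (log2 difference 8.98 ± 0.22, edgeR adjusted p = 1.7e-23). CD99, SERPINB9, IFI16 and STAT6 were higher with CFIm68 by log2 differences of 8.34 ± 0.18, 6.74 ± 0.25, 4.48 ± 0.13 and 4.46 ± 0.10. SLFN12, a Schlafen family gene, had 1 count in all with CFIm68 against 16.3 ± 0.507 CPM with CFIm25 overexpression (ratio 802, 95% exact counting interval 144 to 31722), and ZNF83, PDGFD, TPTE and ZNF667 were 293-fold, 164-fold, 115-fold and 82.6-fold lower with CFIm68. Altogether 7699 genes differed, 3976 higher and 3723 lower, 450 and 728 of them at least 2-fold.

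Direct comparison of the overexpression groups called 7 lists, all with adjusted p = 0.46 with an estimated correlation except where given. With CFIm68, cholesterol synthesis was higher (22 of 27 higher, 2 lower, 3 not past; camera adjusted p = 4.5e-07; adjusted p = 0.36 with an estimated correlation), SQLE at 1.22 ± 0.07. Extracellular matrix (19 of 33 higher, 4 lower, 10 not past; 4.1e-04), oxidative phosphorylation (24 of 38 higher, 2 lower, 12 not past; 9.8e-04) and mitosis genes (24 of 39 higher, 5 lower, 10 not past; 0.0026) were higher as well. Examples were SPARC at 1.92 ± 0.05, CYC1 at 0.99 ± 0.06 (0.04 and not past with the medians of neighbouring genes removed) and BUB1 at 0.76 ± 0.05. ZNF-named genes (51 of 378 higher, 191 lower, 136 not past; camera adjusted p = 1.2e-05; adjusted p = 0.36 with an estimated correlation) were lower. So were the stress list (9 of 33 higher, 21 lower, 3 not past; 0.0026) and neuronal genes (3 of 20 higher, 13 lower, 4 not past; 0.0044; adjusted p = 0.17 with an estimated correlation). Over the list alone, 26 oxidative phosphorylation and 25 mitosis genes were higher and the other counts did not change. Keratinocyte and HeLa-type epithelial genes (1 of 6 higher, 4 lower) and mesenchymal genes (0 of 5 higher, 2 lower) were not called by camera (adjusted p = 0.19 and 0.22). Fry called both as lower with CFIm68 (fry adjusted p = 4.4e-05 and 9.2e-06).

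For each subunit, knockdown and overexpression were also set against each other. For CFIm68 the log2 changes ran in opposite directions (r = -0.26, simulated 0.53; covariance -0.0665, simulated 0.0149). Of 2414 genes past the threshold in both, 249 were higher in both, 292 lower in both and 22.4% went the same way. For CFIm25 the covariance was above that of simulated unchanged groups (0.111 against 0.0148) while r was not (0.39 against 0.50), and 62.9% of all genes had the same sign, against 65.7% simulated. Of 3641 genes past the threshold in both, 1309 were higher in both and 1435 lower in both, 75.4% in all, where independent lists, which leave the shared controls out of account, would share 816 and 813. TSC22D3 and PCDH20 were among them, at 1.60 ± 0.06 and -2.19 ± 0.12 in CFIm25 knockdown and at 2.15 ± 0.06 and -6.11 ± 0.18 in CFIm25 overexpression. With no filter on low counts, r was 0.20 for CFIm68 and 0.25 between the overexpression groups, both of the other sign. These pairs share the 3 control libraries too.

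Chromosome medians shifted against control. For chromosome 3 the genes had a median log2 change of 0.20 in CFIm25 knockdown, 0.19 in CFIm68 knockdown, 0.29 in CFIm25 overexpression and -0.16 in CFIm68 overexpression, and those of chromosome 16 had -0.20, -0.19, -0.18 and 0.10. Chromosome 21 stood at 0.16 and 0.13 in the knockdowns and -0.23 in CFIm25 overexpression, chromosome 8 at 0.06 and 0.05 in the knockdowns and -0.21 in CFIm25 overexpression and chromosome 13 at 0.21 in CFIm68 overexpression. Between the 2 knockdowns no chromosome median exceeded 0.03 in size. Over all 12080 genes the median log2 change lay between -0.00 and 0.01 in these comparisons.

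**Figure D4:**
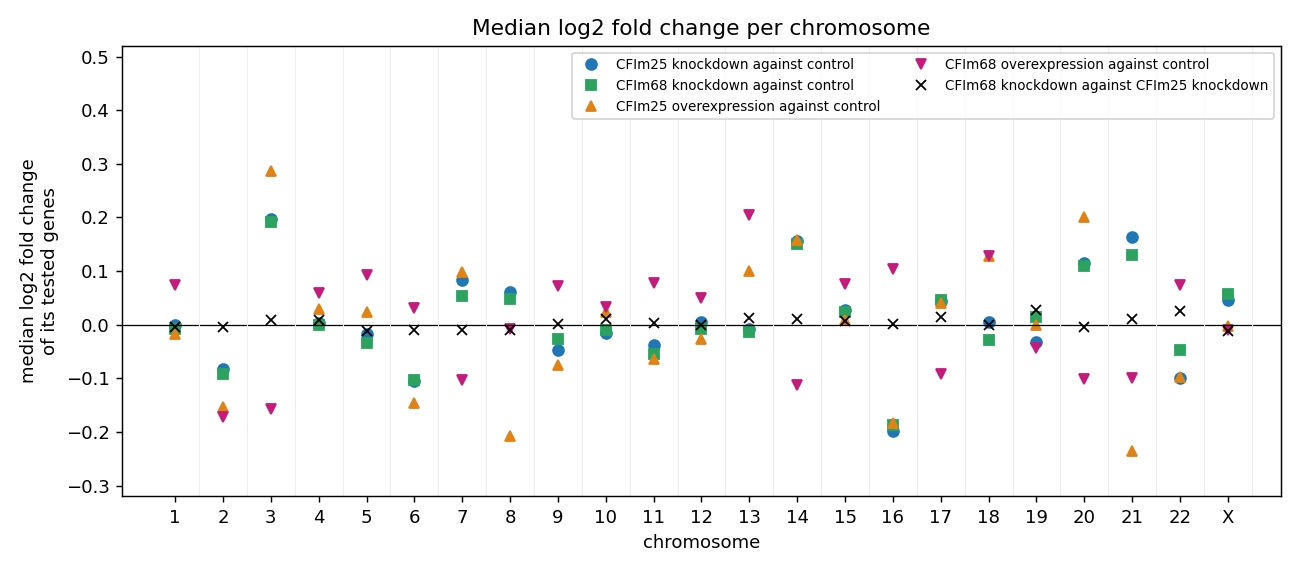
Median log2 fold change of the tested genes of each chromosome (x axis) in the 4 comparisons with control and in the comparison of the 2 knockdowns. Chromosome 3 lies at 0.20, 0.19 and 0.29 in both knockdowns and CFIm25 overexpression and at -0.16 in CFIm68 overexpression, whereas the crosses for CFIm68 against CFIm25 knockdown stay near 0.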

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

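The tests of the control libraries, of a difference of control from all other groups, of a lowered or raised CFIm level, of neighbouring genes, of a mixed sample, of shared controls, of removed window medians and of trends in the shared fold changes were chosen only after the result was seen.

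Some genes differed between perturbations in opposite directions against control, by a test of the difference itself. Between the knockdowns CPSF6 differed by -3.68 (0.99 with CFIm25 and -2.69 with CFIm68 knockdown) and GNPDA1 by -1.57 (0.40 and -1.17). Between the overexpression groups PNMA8A differed by 8.98, SERPINB9 by 6.74, IFI16 by 4.48 and STAT6 by 4.46, all lower than control with CFIm25 and higher with CFIm68. The reverse held for ZNF83, at -8.19, PDGFD, at -7.35, and ZNF667, at -6.37. SLFN12 had a fitted difference of -9.28, which rests on 1 count in CFIm68 overexpression and is no bound. In all, 110 genes past the threshold in both knockdowns and 1437 past it in both overexpression groups went opposite ways.

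Chromosome medians shifted against control, and medians of windows of 50 neighbouring genes correlated at 0.927 between the knockdowns. CFIm25 overexpression shared a part of these shifts. Its medians of chromosome 21 (-0.23, against 0.16 and 0.13 in the knockdowns) and chromosome 8 (-0.21, against 0.06 and 0.05) had the opposite sign, although the last window of chromosome 8 fell in all 3 (-0.71, -0.32 and -0.34). GC content, gene length and expression level are argued against as the whole cause, since the SD of window medians in CFIm25 knockdown was 0.116 with those trends removed, against at most 0.0613 in shuffled gene orders. With CFIm68 overexpression as the second reference, which shares no library with control, the window correlation was 0.780 (shuffled at most 0.149), so control is not the only group that differs. But windows of CFIm68 overexpression ran opposite to those of CFIm25 knockdown (-0.546 to -0.449 with no shared control library), which could give such a value. A shift of control from these 3 groups thus cannot be told apart from a shift they share. A lowered CFIm level as the whole cause of the shared part is argued against. Windows of CFIm25 overexpression and CFIm25 knockdown correlated at 0.725 or more when no control library was shared (the lowest of 6 ways to divide the controls, shuffled at most 0.203). Different chromosome copy number in the cells compared stays open and may explain the shifts: windows 5 apart correlated at 0.516 (shuffled at most 0.217), and the direct comparison of the knockdowns had a window SD of 0.0387, within the shuffled range up to 0.0403. DNA was not measured here.

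Among 9290 genes of at least 5 CPM in control, 8 were at most at 10% of control in CFIm25 overexpression and 10 in CFIm68 overexpression, against 0 by group means in each knockdown, where edgeR called 5746 and 6811 genes. 1 library or a mixed sample is argued against: genes chosen as nearly off in the other libraries of a group were at most at 17.99% of the control mean in the library left out of the choice. A response to the raised CFIm25 level that knockdown would reverse is argued against, since 0 of the 8 genes rose in CFIm25 knockdown (2.11 by chance) and 7 fell. Loss or silencing of neighbouring genes together within 1 Mb is argued against for CFIm25 overexpression: its 8 genes lie on 8 chromosomes, and no other gene of at least 5 CPM in control within 1 Mb, at least 1 for each, was below 46.52% of control. The cause for these 8 genes stays open, since other causes were not tested. Whether the overexpression cells were selected clones is not given in the sources used here. A response to the raised CFIm68 level stays open, since 7 of the 10 genes rose in CFIm68 knockdown (2.98 by chance). The 10 genes are not independent of each other, since 4 of them are neighbours on chromosome 19. But ZNF83, PDGFD and ZNF667, all among the 7, also rose in CFIm25 overexpression (2.12, 1.32 and 1.24). CPSF6 did not pass there, so a rise of these genes is not particular to a lowered CFIm68 level. SLFN12 rose there too (0.89) but did not pass in CFIm68 knockdown (0.24, edgeR adjusted p = 0.061). These 4 were picked above for going opposite ways, so their rise in CFIm25 overexpression came with the choice. Values of the remaining genes in CFIm25 overexpression are not reported here. In CFIm68 overexpression loss or silencing of neighbours together may also contribute, and both can hold at once. There 4 zinc finger genes of chromosome 19 (ZNF83, ZNF468, ZNF808 and ZNF816, named after their values were seen) made all 6 pairs within 1 Mb, against at most 1 in 1000 random draws. The draws leave out of account that zinc finger genes are similar in sequence and can share exonic bases. Around each of the 4, other genes of at least 5 CPM in control within 1 Mb had a median of 88.3% to 99.8% of control. Any joint loss therefore did not cover the whole stretch. STS lies beside PUDP, which was at 10.90% of control and so missed the limit of 10%.

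Fold changes of CFIm25 overexpression went with those of CFIm25 knockdown, although NUDT21 moved in opposite directions. Shared control libraries are argued against as the whole cause, since the correlation was 0.280 to 0.360 over the 6 ways to give each comparison its own control libraries (shuffled at most 0.0298). With no shared control library, chromosome-wide shifts as the whole cause are argued against by 0.238 or more with window medians removed, and GC content, length and level by 0.266 or more with their trends removed. A difference of control from all other groups cannot be told apart from a shared response. With CFIm68 overexpression in place of control in 1 of the 2 comparisons the correlations were 0.437 and 0.294, but CFIm68 overexpression itself ran opposite to CFIm25 knockdown (-0.293 to -0.256 with no shared control library), which could give such values. No biological explanation was tested.

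For groups of 3 against 3 there are 10 splits, too few for a share under 0.05. By edgeR the real split gave 6854 genes for CFIm25 overexpression, 6811 for CFIm68 knockdown, 3605 for CFIm68 overexpression and 7699 between the overexpression groups, and the highest other split gave 0 in each, so 1 split of 10 was as large. For lists, the real and the highest other split gave 9 and 9 (2 splits as large), 3 and 3 (2), 4 and 8 (4), and 7 and 9 (4). The number of called lists therefore does not set the real grouping apart in any of these comparisons.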

How the results depend on the processing

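The settings with window medians removed and with further references were chosen only after the result was seen. Counts of changed genes stayed within 1.5 times under the other scaling, both other filters, DESeq2, limma-voom and fits to the compared groups alone, and the 188 values of named genes kept direction and side of the threshold under these. With window medians removed 180 did so, 5 no longer passed, and 3 changed sign: CPSF7 in CFIm25 overexpression, which then passed as a rise (0.13, adjusted p = 0.032), and AGO2 (0.12) in CFIm25 overexpression and SSU72 (0.035) in CFIm68 knockdown, which did not pass; the count for CFIm68 overexpression was 2269. Genes that also passed against CFIm25 overexpression numbered 2998 for CFIm25 and 4234 for CFIm68 knockdown, and against both overexpression groups 2654 and 3729, by construction fewer.

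With an estimated correlation camera called 0 lists in every comparison, where fry called 14 for CFIm25 knockdown, 17 for CFIm25 overexpression, 13 for CFIm68 knockdown, 11 for CFIm68 overexpression, and 9 and 21 in the direct comparisons. Fitting the compared groups alone left 2 lists between the knockdowns. With no filter the correlation was 0.673 between the knockdowns, 0.462 for CFIm25, and of the other sign for CFIm68 (0.204) and between the overexpression groups (0.250), where the stricter filter gave -0.1001. With window medians removed the last 3 pairs had 0.353, -0.239 and -0.046. Except where the construction shows it, the cause was not tested.

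Leaving out 1 library gave 4363 to 5282 genes for CFIm25 knockdown, 6204 to 6531 for CFIm25 overexpression, 6085 to 6289 for CFIm68 knockdown, 2774 to 3366 for CFIm68 overexpression, 1465 (without CFIm25 knockdown replicate 1) to 2384 between the knockdowns and 7167 to 7424 between the overexpression groups. In the same order 3 to 5, 8 to 10, 2 to 4, 4 to 5, 3 to 4 and 7 to 7 lists were called. Correlations were 0.750 to 0.841 between the knockdowns, -0.088 to -0.033 between the overexpression groups, 0.337 to 0.420 for CFIm25 and -0.270 to -0.205 for CFIm68. A lone CFIm25 knockdown library was assumed to vary like the other groups.

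Replicate numbers paired the libraries weakly at most. Of 26 same-number pairs 3 had r over 0.1, where the highest different-number pair had 0.084. The median r was 0.020 for same-number and -0.006 for different-number pairs, and 8 of 14 libraries correlated best with their own number. As a block they gave 5890, 7128, 7103, 4064, 3256 and 7921 genes, more than without the block in each comparison, and 2 of 33 list calls were lost. A weak pairing is therefore not excluded.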

Other observations

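The test of 3' UTR length and the comparison with further references were chosen only after the result was seen, and the genes named here were chosen after their values were seen.

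Measured against control and both overexpression groups alike, 2000 of 12080 genes changed in the same direction in both knockdowns, 1086 higher and 914 lower, with 41 and 85 at least 2-fold in each comparison. Among genes with a mean of at least 5 CPM over all libraries, the higher ones were led by VMA21, whose smallest log2 change was 1.78, MGAT4A (1.42), CCND2 (1.31), OPN3, which encodes an opsin (1.30), and the metallothionein gene MT2A (1.28). The lower ones were led by PRSS53 (-1.93), the lysosomal transporter gene MFSD8 (-1.77), HNRNPLL (-1.73), the collagen-like gene COLQ (-1.72), the peptidase gene DPP7 (-1.69) and the anchoring collagen gene COL7A1 (-1.67). Of the ribosomal protein list 39 of 73 were in the higher part and 0 in the lower, of published CFIm targets 8 and 1 of 12, of the microRNA pathway 7 and 1 of 28, and of the unfolded protein and ATF4 stress list 0 of 33. Further references do not remove an effect of siRNA transfection that both knockdowns share, and whether the other groups were transfected is not given.

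Of genes changed in CFIm25 knockdown, 52.2% passed in the same direction against CFIm25 overexpression and 85.3% against CFIm68 overexpression. For CFIm68 knockdown the shares were 62.2% and 85.7%.

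Annotated 3' UTR length was compared with fold change over 11892 genes, which are not independent replicates. Given GC content, length and level, the rank correlation was -0.0259 in CFIm25 knockdown and 0.0266 in CFIm68 knockdown, which is no clear trend. The length taken out is that of the whole transcript, 3' UTR included. These values therefore cannot decide whether genes with longer annotated 3' UTRs rise in the knockdowns. Without those terms the values were 0.080 and 0.101.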
